A study of Mus musculus with 16 samples.

How the data were processed

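Total RNA from whole embryonic hearts of mice on a mixed C57/BL6;129Ola background was extracted with Trizol, cleaned on RNeasy columns and turned into biotin-labelled cRNA with a TotalPrep kit, per the labels. The cRNA was hybridised to 16 arrays on 2 Illumina beadchips, on which beads carry a probe for a transcript and the brightness of a probe's beads reports how much of that transcript was present. Beadchip 1 held 2 arrays each of control, KO, DKO and hetDKO. Beadchip 2 held 2 arrays each of control, DKO and DKOhet and 1 array each of KO and hetDKO. The groups were taken from the genotype labels. The labels do not say that each array is a separate embryo, so the p-values measure only the spread between these samples, which may be technical in part; Xist and Eif2s3y separate male from female arrays within each group, so no group is a single embryo.

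The deposited table of non-normalised values gives for each of 25696 probes an average bead intensity per array on a linear scale, with no background taken off, per the file headers and the values. It also gives a detection p-value per probe and array, which compares the probe with the array's own negative control beads, per the file headers. The submitters' processing notes name BeadStudio; its version and settings are not given in the sources used here. The deposited value table of the authors holds 14788 probes as intensity on a linear scale. Its columns share their quantiles, with medians of 594.4 to 594.5, and each follows its own array of the non-normalised table with r of at least 0.9998, so scale and direction are settled and no centring on genes was found. How the authors made that normalisation is not given in the sources used here. The probes in the value table are those with a detection p under 0.05 on at least 1 array. It was used only as an alternative.

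Background was removed with limma's normexp model (nec, which infers the background from the detection p-values), an offset of 16 was added, and the arrays were quantile normalised and put on the log2 scale. Values called signal are on this scale, on which a difference of 1 is a doubling; the offset makes folds of dim probes smaller than they were. Probes with a detection p under 0.05 on at least 2 of the 16 arrays were kept, which left 14058 and took out 11638. Probe names came from a platform annotation in which each annotated probe has 1 gene symbol and none has several. Of the kept probes, 13238 (94.2%) had 1 symbol and 820 had none. No probe carried the symbol Rbpj or Axin2, so the targeted genes were not analysed here and could not be used to check the labels. Where the probes lie within their transcripts was not analysed here. Gene positions are from the GRCm38 annotation.

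A linear model with 1 mean per group was fitted to all 16 arrays with limma, so that the 5 groups share 1 estimate of the spread per probe (11 residual and 3.52 prior degrees of freedom after eBayes). The 7 contrasts were read from it, and p-values were adjusted by Benjamini-Hochberg over all kept probes within each, with calls at an adjusted p under 0.05. All adjusted p-values of genes are from this limma fit and are two-sided. On simulated arrays with 50 probes changed at each size, a change of 1 on the log2 scale was recovered for 72% of probes in KO against control, 80% in DKO against control, 80% in hetDKO against control, 74% in DKOhet against control, 62% in DKO against KO, 64% in DKO against hetDKO and 64% in DKO against DKOhet. For a change of 0.5 the shares were, in the same order, 20%, 30%, 22%, 10%, 20%, 12% and 8%. For a change of 2 they were 90%, 98%, 90%, 96%, 100%, 98% and 94%, and for a change of 3 they were 100%, 100%, 96%, 100%, 100%, 98% and 96%. The number of arrays limits the precision.

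The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where a sentence says otherwise. For each comparison with control, the rule took the 10 largest positive and the 10 largest negative log2 changes among genes past the threshold, with every mutant array beyond every control array and the probe detected on all arrays of the higher group. Between mutants it took 5 each way, filled by the smallest unadjusted p where fewer passed. In each list it took up to 4 members with the smallest p and any member past the threshold. Sex-linked transcripts were kept apart. Where a probe was not above background on any array of a group, only a lower bound of the fold is given, against the lowest signal among the detected probes of each array, or the signal of the probe itself where that was higher.

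There were 25 gene lists. They cover Notch target genes, Notch pathway components, Wnt/beta-catenin target genes, Wnt pathway components, BMP ligands and target genes, the second heart field and pharyngeal mesoderm, and cardiac transcription factors. For muscle and the other cells of the heart they cover chamber and trabecular myocardium, the sarcomere, endocardium and endothelium, cushion mesenchyme, epicardium and proepicardium, and smooth muscle. For cells that could be carried along they cover neural crest, foregut and surface epithelium, hepatic and yolk sac endoderm, erythroid cells, and macrophages and other blood cells. The rest are the cell cycle, hypoxia and glycolysis, p53 target genes, the unfolded protein and amino acid stress response, oxidative phosphorylation, immediate early genes and sex-linked transcripts. Each gene was represented by the probe with the highest mean (9697 genes). The shift of a list against all other genes was tested with camera in limma at a correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry are given beside it. Fry tests a list against no change, not against the other genes.

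The alternatives were no background correction, cyclic loess, median scaling, the deposited value table, no filter, a stricter filter (detection p under 0.01 on at least 4 arrays), beadchip as a block, each beadchip alone, the replicate number as a block, trended and robust variance, array weights, only the arrays of the groups compared, each array left out in turn, and other probes of the same gene. A covariate for the level of Eif2s3y and a covariate for the mean of the erythroid list were added after the data were seen. Correlations between comparisons that share the control arrays were set beside 100 simulations of unchanged groups. Overlaps of calls with no control array in common were added after the data were seen. Software was R 4.3.3, limma 3.58.1 and matplotlib 3.10.9.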

Results

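Gene expression was measured in whole embryonic hearts of mice at E9.25 (22 to 24 somites), when the heart is a looped tube that is forming its chambers. Control hearts (n = 4) were set against 4 mutant genotypes. KO hearts (n = 3) had Rbpj, the DNA-binding protein through which Notch signals reach the genome, deleted by MesP1-cre, which acts in early mesoderm including the precursors of the heart. DKO hearts (n = 4) had the same deletion and no Axin2, a scaffold of the complex that degrades beta-catenin and so a brake on Wnt signalling. HetDKO hearts (n = 3) lacked Axin2 and had 1 floxed copy of Rbpj, and DKOhet hearts (n = 2) had the Rbpj deletion and lacked 1 copy of Axin2. Each array detected between 12360 and 13196 of its 25696 probes, with median signals of 171 to 211.65 before normalisation.

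Hearts with the Rbpj deletion stood apart from the others along the first principal component, which held 28.3% of the variance. Control arrays lay between -29.19 and -23.09 on it and hetDKO arrays between -24.40 and -21.20. KO arrays lay between 10.75 and 22.53, DKO arrays between 12.36 and 30.05, and DKOhet arrays between 17.36 and 31.31. On the second component (15.3%) every array with an odd replicate number had a positive score (5.12 to 23.59) and every array with an even number a negative one. Beadchip 1 held only odd numbers, and beadchip 2 only even numbers except for DKOhet replicate 1 (11.15). The third (11.6%) set 1 array apart, KO replicate 2 at 45.8, against a next highest score of 15.9.

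**Figure D1:**
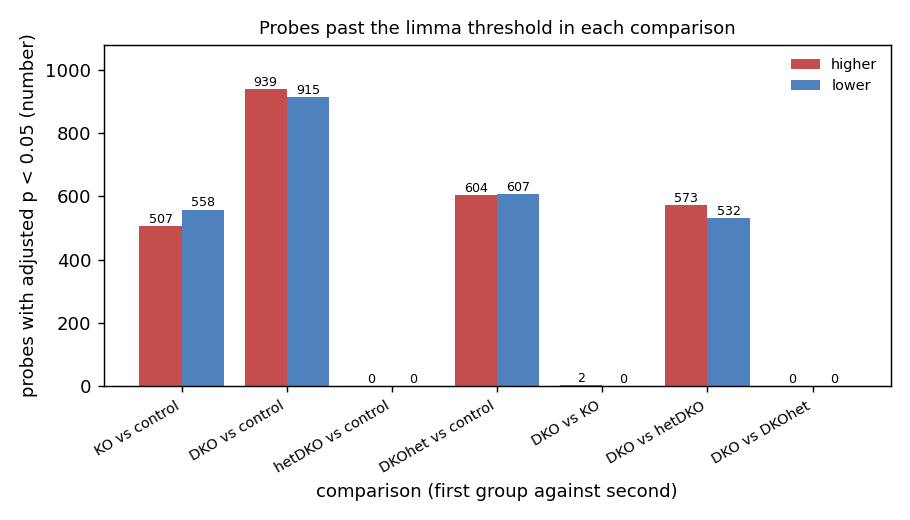
Number of probes past the limma threshold (vertical axis) in each of the 7 comparisons (horizontal axis), with red bars for probes higher and blue bars for probes lower in the first group. The bars reach 939 higher and 915 lower in DKO against control, and hetDKO against control and DKO against DKOhet have no probe past the threshold.

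The comparison of KO with control asks what the loss of Rbpj in the mesoderm changes in the early heart. Chac1, which degrades glutathione and is induced by amino acid stress, had a log2 signal of 11.38 ± 0.66 (SD, n = 3) in KO hearts against 7.23 ± 0.38 (SD, n = 4) in control hearts, 17.7-fold higher (limma adjusted p = 0.000136). Nrn1, a membrane-anchored neuritin, rose 12.8-fold and was detected on 1 of the 4 control arrays. Bhlhe40, a transcriptional repressor that responds to low oxygen, rose 9.30-fold (11.79 ± 0.20 against 8.57 ± 0.26, adjusted p = 5.81e-06), Ndrg1, a hypoxia-responsive gene, rose 8.08-fold, and Stc2, a secreted glycoprotein, rose 7.48-fold. In the other direction, Gja5, which encodes the gap junction protein connexin 40 of atrial and trabecular muscle, had a signal of 7.11 ± 0.49 against 9.76 ± 0.15, 6.27-fold lower (adjusted p = 2.79e-05). Dbx1, a homeobox gene of neural progenitors, was 6.45-fold lower (6.57 ± 0.35 against 9.26 ± 0.39, adjusted p = 0.000637). Its probe was detected on 1 of 3 KO, 1 of 4 DKO and 1 of 2 DKOhet arrays. The size of its fall in these groups therefore rests on values near background.

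Chac1 lies on chromosome 2 at 119351242 to 119354326 and Gja5 on chromosome 3 at 97032402 to 97053634 in GRCm38. Chac1 was higher by 4.12 with beadchip as a block, by 4.83 within beadchip 1 and by 3.09 within beadchip 2, where KO has 1 array and the difference did not pass (adjusted p = 0.126). Gja5 changed by -2.60 with beadchip as a block, by -2.55 within beadchip 1 and by -2.73 within beadchip 2. The fall of Gja5 rests on 1 probe, since its second probe, ILMN_2678477, changed by -0.07 in KO and did not pass.

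Genes of the response to low oxygen and of glycolysis were higher in KO hearts. Of the 23 measured members of the hypoxia and glycolysis list, 16 rose, none fell and 7 did not pass the test, and 17 rose when adjusted over the list alone. Vegfa, the main growth factor of blood vessels, had a signal of 12.54 ± 0.42 against 10.93 ± 0.19, 3.06-fold higher (adjusted p = 0.000512). Egln3, an oxygen sensor, rose 4.99-fold, Ddit4, an inhibitor of mTORC1, rose 5.65-fold, and Pdk1, which inhibits pyruvate dehydrogenase, rose 2.25-fold. The list mean was 1.18 higher (camera adjusted p = 6.43e-20, and adjusted p = 0.0235 with an estimated correlation). It was 1.19 higher with beadchip as a block, 1.35 within beadchip 1 and 0.93 within beadchip 2.

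Immediate early genes, which cells switch on within minutes of a stimulus, were higher in KO hearts too. Of 11 measured, 5 rose and 6 did not pass, and 6 rose when adjusted over the list alone. Egr1 rose 4.03-fold (11.12 ± 0.64 against 9.11 ± 0.40), Fos 3.22-fold and Ier3 6.16-fold. Their mean was 0.999 higher (camera adjusted p = 7.66e-07, and adjusted p = 0.0755 with an estimated correlation), 0.991 with beadchip as a block, 1.003 within beadchip 1 and 0.987 within beadchip 2. Of 19 members of the unfolded protein and amino acid stress response list, 6 rose, 1 fell and 12 did not pass; 7 rose and 1 fell when adjusted over the list alone. Its leading members were Chac1 and Vldlr, a lipoprotein receptor, which rose 5.39-fold. The list mean was 0.90 higher (camera adjusted p = 0.000126, and adjusted p = 0.673 with an estimated correlation), 0.86 with beadchip as a block, 1.14 within beadchip 1 and 0.49 within beadchip 2, where it did not pass (adjusted p = 0.262).

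Some markers of the outer layer of the heart and of endothelium rose in KO hearts. Krt19, a keratin on the epicardium list, had a signal of 10.20 ± 0.27 against 8.27 ± 0.23, 3.82-fold higher (adjusted p = 0.000112). Sox17, an endothelial transcription factor, rose 2.37-fold and its relative Sox7 rose by 0.89. Of 11 epicardium and proepicardium genes, 2 rose and 9 did not pass, and 3 rose when adjusted over the list alone; the list mean was 0.76 higher (camera adjusted p = 0.00135, and adjusted p = 0.327 with an estimated correlation). It was 0.71 higher with beadchip as a block, 0.79 within beadchip 1 and 0.56 within beadchip 2 (adjusted p = 0.0669). Of 29 endocardium and endothelium genes, 2 rose and 27 did not pass, 4 rose when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.590; its median was -0.04 and its mean 0.06).

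Sarcomere and cell cycle genes had lower means in KO hearts. None of 27 sarcomere genes passed, over all genes or adjusted over the list alone, and the list median was -0.41 (camera adjusted p = 0.00203, and adjusted p = 0.868 with an estimated correlation). The sarcomere mean was -0.42, -0.34 with beadchip as a block, -0.28 within beadchip 1 (adjusted p = 0.0634) and -0.40 within beadchip 2. This call was lost without control replicate 4 (-0.29), without KO replicate 1 (-0.14) or with the erythroid covariate (-0.24). Of 23 cell cycle genes 3 fell and 20 did not pass, also when adjusted over the list alone, with a mean of -0.20 (camera adjusted p = 0.00988, and adjusted p = 0.303 with an estimated correlation). That mean was -0.19 with beadchip as a block, -0.20 within beadchip 1 and -0.18 within beadchip 2 (adjusted p = 0.103). The threshold was missed without control replicate 4 (-0.17).

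None of the 14 measured Notch target genes passed the test in KO hearts, over all genes or adjusted over the list alone. The list did not pass either (mean -0.13, 6 of 14 positive, camera adjusted p = 0.590). Small changes could be missed, since a change of 0.5 was recovered for 20% of simulated probes in this comparison. That share is a low estimate, because the simulation called 147 probes and the data 1065, which makes the adjustment stricter in the simulation. Nrarp, a feedback inhibitor of Notch, had a signal of 11.09 ± 0.15 against 11.62 ± 0.34 and a log2 difference of -0.53 (adjusted p = 0.105). Its KO arrays (10.99 to 11.26) all lay below its control arrays (11.33 to 12.12). Hes5 differed by -0.58 and the glycosyltransferase Lfng by -0.50, neither past the threshold. Of 21 Notch pathway components 1 fell and 20 did not pass (camera adjusted p = 0.846).

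In all, 1065 probes passed in KO against control, 507 higher and 558 lower, and of the 213 that also differed at least 2-fold 144 were higher. The balance moved with the scaling, with 545 higher and 476 lower under cyclic loess (53.4% higher) and 429 higher and 654 lower under median scaling (39.6% higher). The count was 1390 with beadchip as a block, 253 within beadchip 1 (177 higher) and 95 within beadchip 2 (80 higher). It was 677 without control replicate 1, 630 without control replicate 3, 607 without KO replicate 1, 685 without KO replicate 2 and 591 without KO replicate 3. Erythroid genes varied widely among these hearts, with Hbb-b2, a globin, at 10.13 ± 2.18 in KO against 7.62 ± 0.79 (adjusted p = 0.0641) and a list that did not pass (camera adjusted p = 0.287).

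**Figure D2:**
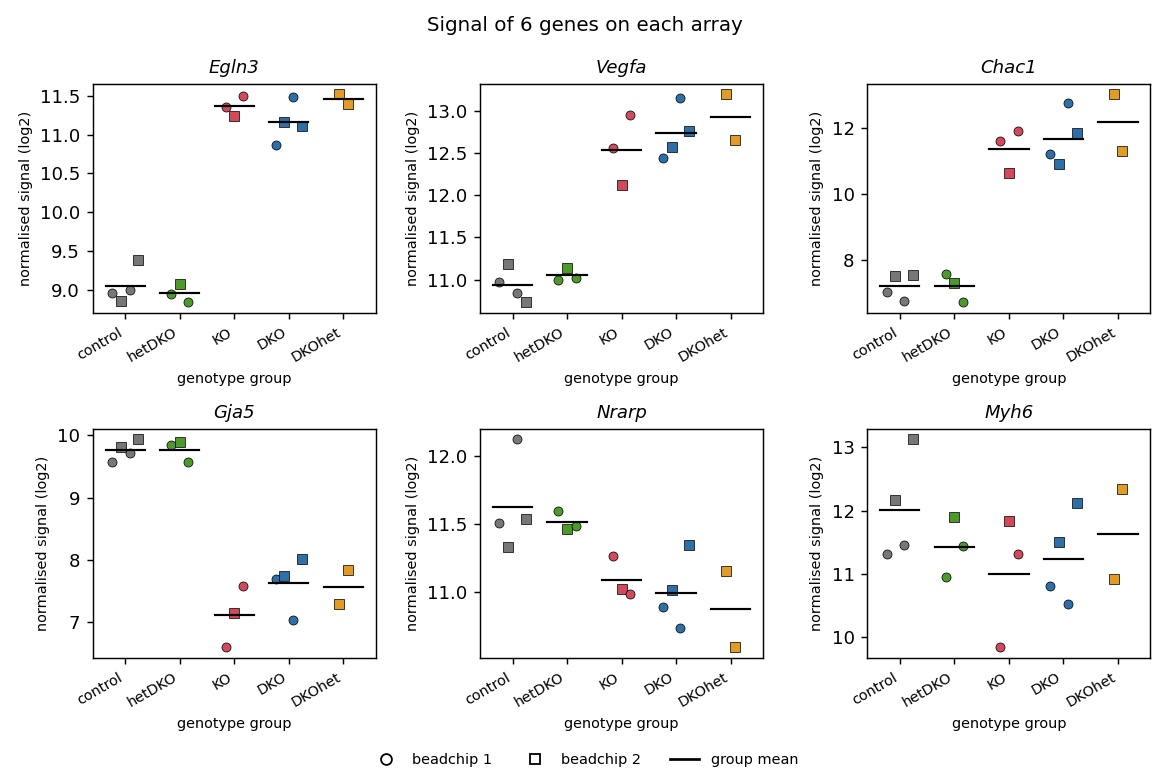
Normalised log2 signal (vertical axes) of 6 genes on each of the 16 arrays, by genotype group, with circles for beadchip 1, squares for beadchip 2 and a line at the group mean. Egln3 lies between 8.85 and 9.38 in control and 8.84 and 9.07 in hetDKO hearts, and between 10.86 and 11.52 in KO, DKO and DKOhet hearts.

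The comparison of DKO with control asks what the loss of Rbpj in the mesoderm together with the loss of Axin2 changes. Chac1 had a signal of 11.68 ± 0.82 (SD, n = 4) against 7.23 ± 0.38 (SD, n = 4), 21.9-fold higher (limma adjusted p = 2.56e-05). Nrn1 rose 15.8-fold, Bhlhe40 9.36-fold, Ndrg1 8.46-fold and Vldlr 7.76-fold (11.96 ± 0.27 against 9.01 ± 0.36, adjusted p = 1.36e-06). Car9, a carbonic anhydrase induced by hypoxia, was not above background on any control array and was at least 5.01-fold higher in DKO hearts. Dbx1, detected on 1 of the 4 DKO arrays, was 7.53-fold lower, and Gja5 was 4.39-fold lower (7.63 ± 0.41 against 9.76 ± 0.15, adjusted p = 6.05e-05). Foxe1, a forkhead gene of the pharyngeal endoderm and thyroid, fell by 1.43 on the log2 scale, and Vgll2, a cofactor of TEAD proteins in muscle, fell by 1.58.

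Chac1 was higher by 5.08 within beadchip 1 and by 3.83 within beadchip 2 (adjusted p = 0.0763), and by 4.45 with beadchip as a block. Gja5 changed by -2.28 within beadchip 1, by -1.99 within beadchip 2 and by -2.13 with beadchip as a block. Its second probe, ILMN_2678477, differed by -0.25 in DKO and did not pass.

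Wnt target genes were higher in DKO hearts. Of 18 measured, 6 rose, none fell and 12 did not pass, and 8 rose when adjusted over the list alone. Sp5, a transcription factor that Wnt induces, had a signal of 11.77 ± 0.36 against 10.79 ± 0.34, 1.98-fold higher (adjusted p = 0.00648). Notum, a secreted enzyme that inactivates Wnt ligands, had a signal of 8.50 ± 0.44 against 6.91 ± 0.58, 3.01-fold higher (adjusted p = 0.0136). The list mean was 0.51 higher (camera adjusted p = 0.000353, and adjusted p = 0.189 with an estimated correlation) and the same with beadchip as a block, 0.59 within beadchip 1 and 0.43 within beadchip 2. Of 26 Wnt pathway components 3 rose and 23 did not pass, also when adjusted over the list alone, among them Dkk3, which rose by 0.52, and the receptor Fzd1, which rose by 1.02; the list did not pass (camera adjusted p = 0.147).

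BMP and cushion genes were higher in DKO hearts as lists, with few single genes past the threshold. Of 14 BMP ligands and target genes 1 rose and 13 did not pass, and 2 rose when adjusted over the list alone; the gene was Grem1, a BMP antagonist (7.18 ± 0.34 against 6.42 ± 0.20, 0.77 higher, adjusted p = 0.0119). The BMP mean was 0.30 higher (camera adjusted p = 0.00889, and adjusted p = 0.231 with an estimated correlation), also 0.30 with beadchip as a block, 0.34 within beadchip 1 and 0.27 within beadchip 2 (adjusted p = 0.0596). It did not pass without DKO replicate 3 (0.23, adjusted p = 0.0575) or with the stricter filter (0.26). Of 19 cushion mesenchyme genes 1 rose and 18 did not pass, also when adjusted over the list alone; it was Pdgfra, a growth factor receptor, which rose by 0.62. The cushion mean was 0.42 higher (camera adjusted p = 0.00557, and adjusted p = 0.231 with an estimated correlation), the same with beadchip as a block, 0.51 within beadchip 1 and 0.33 within beadchip 2.

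Hypoxia and glycolysis genes were higher in DKO hearts, with 17 of 23 members that rose and 6 that did not pass, and 17 that rose when adjusted over the list alone. Vegfa rose 3.50-fold, Ddit4 5.43-fold, Pdk1 2.43-fold and Egln3 by 2.11, with ILMN_2782101, a dimmer Egln3 probe, at 0.77 and not past. The list mean was 1.22 higher (camera adjusted p = 3.80e-19, and adjusted p = 0.0272 with an estimated correlation), 1.22 with beadchip as a block, 1.31 within beadchip 1 and 1.13 within beadchip 2. Of 11 immediate early genes 7 rose and 4 did not pass, and 9 rose when adjusted over the list alone, led by Fos, which rose 3.35-fold, and Egr1, which rose 3.74-fold. Their mean was 0.99 higher (camera adjusted p = 2.60e-06, and adjusted p = 0.0968 with an estimated correlation), 0.99 with beadchip as a block, 1.04 within beadchip 1 and 0.93 within beadchip 2. Of 19 unfolded protein and amino acid stress genes 5 rose and 14 did not pass, and 8 rose when adjusted over the list alone, among them Atf3, a stress-induced transcription factor, which rose by 0.997. That mean was 0.83 higher (camera adjusted p = 0.000931, and adjusted p = 0.461 with an estimated correlation), 0.83 with beadchip as a block, 1.17 within beadchip 1 and 0.48 within beadchip 2, where it did not pass (adjusted p = 0.152).

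Of the cardiac transcription factors, Gata6 rose by 0.82 (12.68 ± 0.39 against 11.86 ± 0.11, adjusted p = 0.0108) and Mef2a by 0.61. Smyd1, a muscle histone methyltransferase, fell by 0.92, and the other 20 of 23 did not pass. When adjusted over the list alone 3 rose and 1 fell, and the list did not pass (camera adjusted p = 0.576). Krt19 rose by 1.63 and was 1 of 2 epicardium genes that rose among 11, with 3 when adjusted over the list alone. The epicardium mean was 0.77 higher (camera adjusted p = 0.00172, and adjusted p = 0.231 with an estimated correlation), 0.77 with beadchip as a block, 0.90 within beadchip 1 and 0.64 within beadchip 2. Sox17 rose by 1.34 and Sox7 by 0.88, with 3 of 29 endothelial genes risen and 26 not past, 2 when adjusted over the list alone (camera adjusted p = 0.576). Of 23 cell cycle genes 3 fell and 20 did not pass, and 8 fell when adjusted over the list alone; Rrm2, a subunit of the enzyme that makes deoxynucleotides, fell by 1.01, although its other probe ILMN_2819319 differed by -0.47 and did not pass. The cell cycle mean was -0.25 (camera adjusted p = 0.00240, and adjusted p = 0.173 with an estimated correlation), -0.25 with beadchip as a block, -0.29 within beadchip 1 and -0.21 within beadchip 2.

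Of 14 Notch target genes, 2 fell in DKO hearts and 12 did not pass, also when adjusted over the list alone (camera adjusted p = 0.673). Hes5, a transcriptional repressor that Notch induces, had a signal of 8.15 ± 0.77 against 9.41 ± 0.54 and fell by 1.26 (adjusted p = 0.0205). Its call ended without control replicate 3 (-1.11, adjusted p = 0.0627) or DKO replicate 3 (-1.25, adjusted p = 0.0513). Nrarp fell by 0.63 (adjusted p = 0.0324). Nrarp did not pass without control replicate 1 (-0.67), control replicate 3 (-0.46), DKO replicate 1 (-0.59), DKO replicate 2 (-0.64) or DKO replicate 3 (-0.54). Within beadchip 1 neither passed (Hes5 -1.21, adjusted p = 0.0601, and Nrarp -1.001, adjusted p = 0.0549). Nor did they within beadchip 2 (Hes5 -1.31, adjusted p = 0.426, and Nrarp -0.26, adjusted p = 0.6996).

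Erythroid genes had lower values in DKO than in control hearts, with 0 of 19 past the threshold, over all genes or adjusted over the list alone, and a list median of -0.93. The erythroid mean was -0.73 (camera adjusted p = 0.00306, and adjusted p = 0.727 with an estimated correlation), -0.73 with beadchip as a block, -0.72 within beadchip 1 and -0.74 within beadchip 2. This call was lost without DKO replicate 2 (-0.50), and without control replicate 3 the mean was -0.45. Of 27 oxidative phosphorylation genes 1 fell and 26 did not pass, with none when adjusted over the list alone, and the mean was -0.13 (camera adjusted p = 0.0356, and adjusted p = 0.283 with an estimated correlation). That mean was -0.13 with beadchip as a block, -0.09 within beadchip 1 (adjusted p = 0.269) and -0.17 within beadchip 2. The threshold was missed without control replicate 4 (-0.07), DKO replicate 1 (-0.11) or DKO replicate 2 (-0.13), and with the stricter filter (-0.125), array weights (-0.09), the Eif2s3y covariate (-0.12) or the erythroid covariate (-0.14).

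In all, 1854 probes passed in DKO against control, 939 higher and 915 lower, and of the 228 that also differed at least 2-fold 175 were higher. The count was 2319 with beadchip as a block, 456 within beadchip 1 (295 higher) and 22 within beadchip 2 (16 higher), and it was 1139 without control replicate 3 and 1040 without DKO replicate 3.

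**Figure D3:**
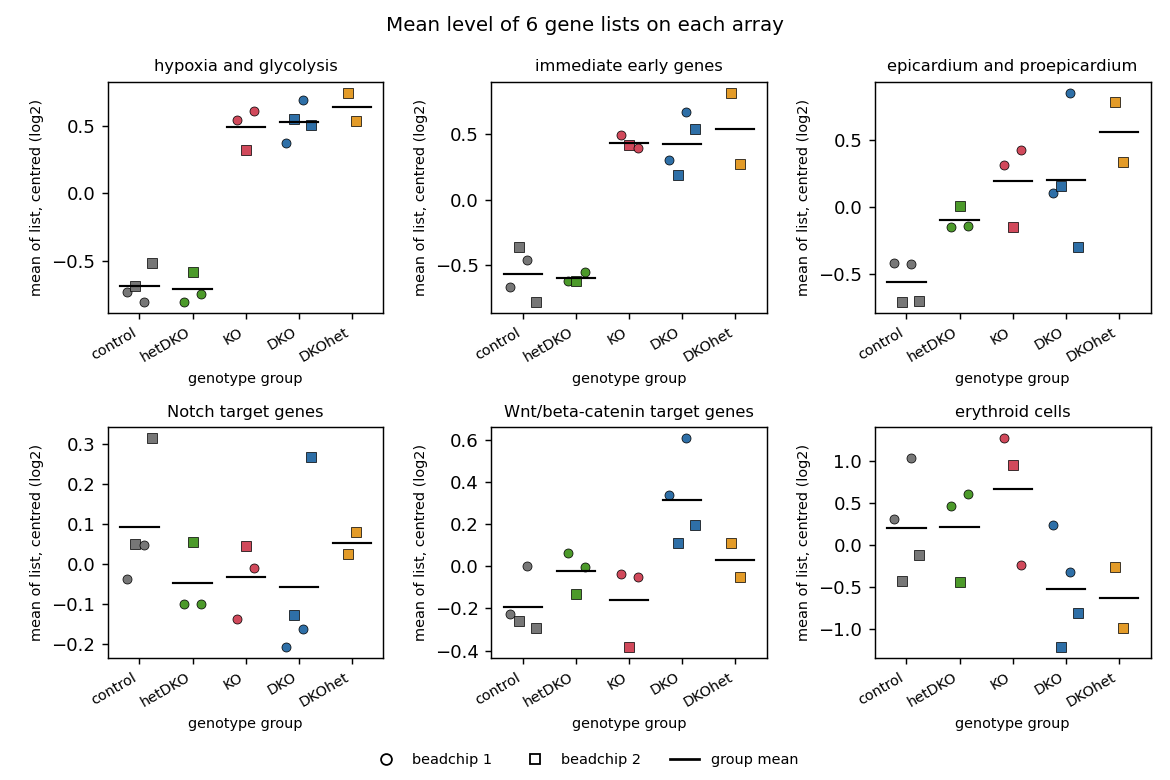
Mean centred log2 signal (vertical axes) of 6 gene lists on each of the 16 arrays, by genotype group, with circles for beadchip 1, squares for beadchip 2 and a line at the group mean. The hypoxia and glycolysis list was higher by 1.18 in KO, 1.22 in DKO and 1.33 in DKOhet hearts than in control hearts.

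DKOhet hearts, with the Rbpj deletion and 1 copy of Axin2 lost, were all on beadchip 2, and against control they show the loss of Rbpj and of 1 Axin2 copy together. Chac1 had a signal of 12.17 ± 1.22 (SD, n = 2) against 7.23 ± 0.38 (SD, n = 4), 30.6-fold higher (limma adjusted p = 0.000118), a log2 difference of 4.94 that was 4.08 without DKOhet replicate 1 and 5.80 without DKOhet replicate 2. Nrn1 rose 16.6-fold, Stc2 9.21-fold, Cox4i2, a cytochrome oxidase subunit used at low oxygen, 8.97-fold, Vldlr 8.64-fold and Nxph4, a neurexophilin, 7.30-fold. Dbx1 fell by 2.66 on the log2 scale and Gja5 was 4.57-fold lower (7.57 ± 0.39 against 9.76 ± 0.15, adjusted p = 0.000455), with ILMN_2678477, the second Gja5 probe, at -0.36 and not past. Within beadchip 2 Chac1 was higher by 4.62 and Gja5 changed by -2.30, and with beadchip as a block they changed by 5.03 and -2.32. All fits by beadchip place DKOhet replicate 1 with beadchip 2, although on the second principal component it lay with the beadchip 1 arrays. This limits each such value of DKOhet hearts, also in DKO against DKOhet.

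Of 23 hypoxia and glycolysis genes 16 rose and 7 did not pass, and 18 rose when adjusted over the list alone, among them Vegfa (12.93 ± 0.39 against 10.93 ± 0.19, adjusted p = 0.000266) and Egln3, which rose 5.32-fold. Their mean was 1.33 higher (camera adjusted p = 1.89e-19, and adjusted p = 0.0256 with an estimated correlation), 1.31 with beadchip as a block and 1.25 within beadchip 2. Of 11 immediate early genes 6 rose and 5 did not pass, and 7 rose when adjusted over the list alone; Fos rose 4.06-fold. Their mean was 1.11 within beadchip 2 and 1.13 with beadchip as a block (camera adjusted p = 1.29e-06 over all arrays, and adjusted p = 0.0838 with an estimated correlation). Of 19 unfolded protein and amino acid stress genes 5 rose and 14 did not pass, and 9 rose when adjusted over the list alone, including Atf3, which rose by 1.35. That mean was 1.09 higher (camera adjusted p = 1.94e-05, and adjusted p = 0.293 with an estimated correlation), 1.204 with beadchip as a block and 1.01 within beadchip 2. It did not pass without DKOhet replicate 1 (0.53, adjusted p = 0.0585) and was 1.64 without DKOhet replicate 2.

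Epicardium genes were higher in DKOhet hearts, with 3 of 11 that rose and 8 that did not pass, and 8 that rose when adjusted over the list alone; Krt19 was 3.57-fold higher. Their mean was 1.13 higher (camera adjusted p = 2.68e-05, and adjusted p = 0.129 with an estimated correlation), 1.29 with beadchip as a block and 1.27 within beadchip 2. Of 29 endothelial genes 4 rose and 25 did not pass, also when adjusted over the list alone, led by Sox17, which rose by 1.57 (camera adjusted p = 0.102). Of 19 cushion genes 2 rose and 17 did not pass, also when adjusted over the list alone, with a mean 0.51 higher (camera adjusted p = 0.00499, and adjusted p = 0.267 with an estimated correlation), 0.58 with beadchip as a block and 0.53 within beadchip 2. Its call ended without DKOhet replicate 1 (0.36). Of 14 BMP genes 1 rose and 13 did not pass, with none when adjusted over the list alone, and the mean was 0.29 higher (camera adjusted p = 0.0251, and adjusted p = 0.288 with an estimated correlation), 0.31 with beadchip as a block and within beadchip 2. This call was lost without control replicate 2 (0.27) or DKOhet replicate 1 (0.21). Of 23 cell cycle genes 4 fell and 19 did not pass, and 8 fell when adjusted over the list alone, with a mean of -0.28 (camera adjusted p = 0.00250, and adjusted p = 0.129 with an estimated correlation), -0.31 with beadchip as a block and -0.30 within beadchip 2. The threshold was missed without DKOhet replicate 1 (-0.21).

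Of 18 Wnt target genes 2 rose, 1 fell and 15 did not pass in DKOhet hearts, with 5 and 1 when adjusted over the list alone (camera adjusted p = 0.102), and of 26 Wnt components 2 rose and 24 did not pass, with 3 when adjusted over the list alone (camera adjusted p = 0.0805). Dkk3 rose by 0.73 and did not pass without DKOhet replicate 1 (0.64, adjusted p = 0.0924). Of 14 Notch targets 1 fell and 13 did not pass, with none when adjusted over the list alone (camera adjusted p = 0.974). That was Nrarp, which fell by 0.75 (adjusted p = 0.0482) and did not pass with beadchip as a block (-0.73) or within beadchip 2 (-0.56). Nrarp did not pass without control replicate 1 (-0.79), control replicate 3 (-0.58), DKOhet replicate 1 (-1.03) or DKOhet replicate 2 (-0.47). Erythroid genes had a median of -0.93 with 0 of 19 past, over all genes or adjusted over the list alone. The erythroid mean was -0.82 (camera adjusted p = 0.00499, and adjusted p = 0.719 with an estimated correlation), -0.48 with beadchip as a block (adjusted p = 0.0896) and -0.35 within beadchip 2. Both of these fits place DKOhet replicate 1 with beadchip 2, although on the second principal component it lay with the beadchip 1 arrays. The erythroid list did not pass without DKOhet replicate 2 (-0.46), and without control replicate 3 its mean was -0.55.

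In all, 1211 probes passed in DKOhet against control, 604 higher (49.9%) and 607 lower, with 285 that also differed at least 2-fold; under median scaling 1378 passed, 489 higher (35.5%) and 889 lower. The count was 1453 with beadchip as a block and 27 within beadchip 2 (24 higher), and it was 726 without control replicate 1, 648 without control replicate 3, 227 without DKOhet replicate 1 and 675 without DKOhet replicate 2; without either DKOhet array, the lone sample is assumed to vary like the other groups.

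HetDKO hearts, which lacked Axin2 and kept 1 intact copy of Rbpj, were set against control to ask what the loss of Axin2 changes while Rbpj is present. The genes that led the other comparisons were close to control in them. Egln3 had a signal of 8.95 ± 0.11 (SD, n = 3) against 9.05 ± 0.23 (SD, n = 4), and Vegfa 11.06 ± 0.08 against 10.93 ± 0.19. Among Wnt targets, Notum stood at 7.79 ± 0.47 against 6.91 ± 0.58, a log2 difference of 0.88, and Sp5 at 11.16 ± 0.22 against 10.79 ± 0.34, a difference of 0.38 (limma adjusted p = 0.998 for each). None of 14058 probes passed with limma, against 545 at an unadjusted p under 0.05, where chance gives 703, and none within beadchip 1 or with beadchip as a block; within beadchip 2 hetDKO has 1 array and no probe passed either.

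As lists, epicardium genes were higher and sarcomere genes lower in hetDKO hearts, with 0 of 11 and 0 of 27 members past the threshold, over all genes or adjusted over the list alone. The epicardium mean was 0.47 higher (camera adjusted p = 0.00164, and adjusted p = 0.696 with an estimated correlation), 0.42 with beadchip as a block, 0.28 within beadchip 1 (adjusted p = 0.119) and 0.72 within beadchip 2. Aldh1a2, which makes retinoic acid, differed by 0.73 and Wt1, an epicardial transcription factor, by 0.65. The sarcomere mean was -0.27 (camera adjusted p = 0.00861, and adjusted p = 0.959 with an estimated correlation), -0.20 with beadchip as a block (adjusted p = 0.102), -0.08 within beadchip 1 (adjusted p = 0.821) and -0.38 within beadchip 2, with Myh7, a myosin heavy chain, at -0.94. Its call ended without control replicate 2 (-0.21), control replicate 4 (-0.15) or hetDKO replicate 1 (-0.14). It also ended with array weights (-0.11) or the replicate number as a block. None of 18 Wnt targets (camera adjusted p = 0.162), 14 Notch targets (0.177), 23 hypoxia and glycolysis genes (0.302) or 11 immediate early genes (0.882; median 0.08, mean -0.03) passed, over all genes or adjusted over the list alone.

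DKO against hetDKO asks what the loss of the remaining Rbpj copy changes where Axin2 is absent from both groups. Chac1 had a signal of 11.68 ± 0.82 (SD, n = 4) in DKO against 7.21 ± 0.44 (SD, n = 3) in hetDKO hearts, 22.2-fold higher (limma adjusted p = 6.16e-05). Bhlhe40 rose 9.49-fold, Stc2 8.75-fold and Vldlr 8.39-fold, and Nrn1, not above background on any hetDKO array, was at least 11.7-fold higher. Gja5 was 4.42-fold lower (7.63 ± 0.41 against 9.77 ± 0.17), with its probe ILMN_2678477 at -0.60 and not past, and Dbx1 fell by 2.53. Chac1 was higher by 4.50 with beadchip as a block, 4.82 within beadchip 1 and 4.07 within beadchip 2 (adjusted p = 0.191), and Gja5 changed by -2.19, -2.34 and -2.01 (adjusted p = 0.146) in the same order.

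Of 23 hypoxia and glycolysis genes 16 rose and 7 did not pass, and 18 rose when adjusted over the list alone; Vegfa stood at 12.74 ± 0.31 against 11.06 ± 0.08. Their mean was 1.25 higher (camera adjusted p = 3.40e-21, and adjusted p = 0.0186 with an estimated correlation), 1.24 with beadchip as a block, 1.32 within beadchip 1 and 1.11 within beadchip 2. Of 11 immediate early genes 5 rose and 6 did not pass, and 9 rose when adjusted over the list alone, with a mean 1.02 higher (camera adjusted p = 5.66e-07, and adjusted p = 0.0711 with an estimated correlation), 1.03 with beadchip as a block, 1.07 within beadchip 1 and 0.98 within beadchip 2. Of 19 unfolded protein and amino acid stress genes 5 rose and 14 did not pass, and 6 rose when adjusted over the list alone, with a mean 0.81 higher (camera adjusted p = 0.000367, and adjusted p = 0.432 with an estimated correlation), 0.85 with beadchip as a block, 1.05 within beadchip 1 and 0.61 within beadchip 2. Krt19 rose by 1.53 as the only epicardium gene of 11 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.273). Sox17 rose by 1.04 and Sox7 by 0.95, with 4 of 29 endothelial genes risen and 25 not past, also when adjusted over the list alone (camera adjusted p = 0.283).

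Wnt lists were higher in DKO than in hetDKO hearts, although neither group has Axin2. Of 18 Wnt targets 2 rose and 16 did not pass, also when adjusted over the list alone; Fzd7, a Wnt receptor, stood at 12.72 ± 0.11 against 11.82 ± 0.19, 0.90 higher (adjusted p = 0.00433). The target mean was 0.34 higher (camera adjusted p = 0.00963, and adjusted p = 0.303 with an estimated correlation), 0.38 with beadchip as a block, 0.44 within beadchip 1 and 0.29 within beadchip 2 (adjusted p = 0.0576). Of 26 Wnt components 1 rose, Dkk3, and 25 did not pass, also when adjusted over the list alone, with a mean 0.26 higher (camera adjusted p = 0.0122, and adjusted p = 0.2001 with an estimated correlation), 0.27 with beadchip as a block, 0.34 within beadchip 1 and 0.15 within beadchip 2 (adjusted p = 0.130). Of 14 BMP genes 1 rose and 13 did not pass, with 2 when adjusted over the list alone, and the mean was 0.26 higher (camera adjusted p = 0.0229, and adjusted p = 0.303 with an estimated correlation), 0.27 with beadchip as a block, 0.34 within beadchip 1 and 0.15 within beadchip 2 (adjusted p = 0.309). This call was lost without DKO replicate 3 (0.18) or hetDKO replicate 1 (0.22), or with the stricter filter (0.24). Of 19 cushion genes 3 rose and 16 did not pass, also when adjusted over the list alone, with a mean 0.36 higher (camera adjusted p = 0.0102, and adjusted p = 0.303 with an estimated correlation), 0.38 with beadchip as a block, 0.47 within beadchip 1 and 0.24 within beadchip 2 (adjusted p = 0.0616). Without DKO replicate 3 the cushion mean was 0.24.

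Of 23 cell cycle genes 2 fell between hetDKO and DKO hearts, also when adjusted over the list alone, and 21 did not pass. Rrm2 fell by 0.92, with its other probe ILMN_2819319 at -0.49 and not past. The cell cycle mean was -0.23 (camera adjusted p = 0.0102, and adjusted p = 0.203 with an estimated correlation), -0.24 with beadchip as a block, -0.29 within beadchip 1 and -0.18 within beadchip 2 (adjusted p = 0.0722). Of 27 oxidative phosphorylation genes 2 fell and 25 did not pass, also when adjusted over the list alone, with a mean of -0.19 (camera adjusted p = 0.00686, and adjusted p = 0.203 with an estimated correlation), -0.20 with beadchip as a block, -0.21 within beadchip 1 and -0.17 within beadchip 2 (adjusted p = 0.0616). None of 19 erythroid genes passed, over all genes or adjusted over the list alone, and their mean was -0.74 (camera adjusted p = 0.00563, and adjusted p = 0.726 with an estimated correlation), -0.62 with beadchip as a block, -0.58 within beadchip 1 (adjusted p = 0.0827) and -0.57 within beadchip 2. The erythroid list did not pass without DKO replicate 2 (-0.51).

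In all, 1105 probes passed in DKO against hetDKO, 573 higher and 532 lower, with 188 that also differed at least 2-fold. The count was 1481 with beadchip as a block, 439 within beadchip 1 and 4 within beadchip 2, and it was 691 without DKO replicate 3, 653 without DKO replicate 4, 449 without hetDKO replicate 1, 558 without hetDKO replicate 2 and 476 without hetDKO replicate 3.

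DKO against KO asks what the loss of Axin2 adds once Rbpj is deleted. Wnt target genes were higher in DKO hearts as a list. Of 18 measured, 17 had higher means in DKO hearts, none passed over all genes and 4 rose when adjusted over the list alone. Sp5 stood at 11.77 ± 0.36 (SD, n = 4) against 11.09 ± 0.13 (SD, n = 3), a log2 difference of 0.68, and Notum at 8.50 ± 0.44 against 7.31 ± 0.78, a difference of 1.19 (limma adjusted p = 0.977 for each). Their mean was 0.47 higher (camera adjusted p = 3.25e-10, adjusted p = 0.0478 with an estimated correlation and adjusted p = 0.0776 with fry), 0.51 with beadchip as a block, 0.52 within beadchip 1 and 0.54 within beadchip 2.

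Further lists were higher in DKO than in KO hearts with no member past the threshold, over all genes or adjusted over the list alone. Wnt pathway components (26 genes) were 0.17 higher in the mean (camera adjusted p = 0.0235, and adjusted p = 0.174 with an estimated correlation), 0.19 with beadchip as a block, 0.12 within beadchip 1 (adjusted p = 0.293) and 0.33 within beadchip 2. They did not pass without DKO replicate 3 (0.12), DKO replicate 4 (0.15) or KO replicate 2 (0.07), and were 0.26 without KO replicate 3. Nor did they pass with array weights (0.10), the erythroid covariate (0.13) or the replicate number as a block. BMP genes (14) were 0.16 higher (camera adjusted p = 0.0268, and adjusted p = 0.320 with an estimated correlation), 0.17 with beadchip as a block, 0.22 within beadchip 1 and 0.11 within beadchip 2 (adjusted p = 0.659). They did not pass without DKO replicate 3 (0.09) or KO replicate 1 (0.11). Nor did they with the stricter filter (0.16), the erythroid covariate (0.15) or the replicate number as a block. Genes of the chamber and trabecular myocardium (15) were 0.27 higher (camera adjusted p = 0.00296, and adjusted p = 0.309 with an estimated correlation), 0.24 with beadchip as a block, 0.14 within beadchip 1 (adjusted p = 0.0580) and 0.41 within beadchip 2. They did not pass without KO replicate 1 (0.16). With the erythroid list as a covariate the chamber mean turned to -0.01 (adjusted p = 0.972). Cushion genes (19) were 0.31 higher (camera adjusted p = 0.000667, and adjusted p = 0.174 with an estimated correlation), 0.33 with beadchip as a block, 0.30 within beadchip 1 and 0.44 within beadchip 2. Without DKO replicate 3 the cushion mean was 0.19, and also 0.19 without KO replicate 2.

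Markers of blood cells were lower in DKO than in KO hearts as lists. Of 19 erythroid genes 0 passed over all genes and 1 fell when adjusted over the list alone, with a median of -1.40 and a mean of -1.19 (camera adjusted p = 1.86e-14, and adjusted p = 0.174 with an estimated correlation). The erythroid mean was -1.08 with beadchip as a block, -0.56 within beadchip 1 and -1.97 within beadchip 2, where the 1 KO array is replicate 2. Of 20 macrophage and other blood cell genes 5 were measured and 0 passed, over all genes or adjusted over the list alone, with a mean of -1.23 (camera adjusted p = 0.000346, and adjusted p = 0.174 with an estimated correlation), -1.18 with beadchip as a block, -0.73 within beadchip 1 and -1.97 within beadchip 2. The macrophage list did not pass with the erythroid covariate (-0.50, adjusted p = 0.209).

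Single probes hardly differed between DKO and KO hearts, with 2 past the threshold, both higher in DKO, against 706 at an unadjusted p under 0.05, where chance gives 703. They were named after their values were seen. A probe of Mrpl10, a protein of the mitochondrial ribosome, had a signal of 12.22 ± 0.03 in DKO against 10.14 ± 0.13 in KO hearts, 4.23-fold higher (adjusted p = 5.06e-05). A probe of Lsm12, an RNA-binding protein, had 9.91 ± 0.48 against 6.89 ± 0.73, 8.12-fold higher (adjusted p = 0.0434). Control hearts had the higher signal too, at 12.23 ± 0.34 for the Mrpl10 probe and 9.61 ± 0.92 for the Lsm12 probe, and between DKO and KO other probes of both genes did not follow: the second Mrpl10 probe changed by -0.43 and the 3 other Lsm12 probes by 0.32, 0.07 and -0.04. Against control, ILMN_2730926, another Lsm12 probe, was lower in KO (-0.69, adjusted p = 0.00656), DKO (-0.61, adjusted p = 0.00509) and DKOhet hearts (-0.82, adjusted p = 0.00516), and ILMN_2963580 in DKOhet hearts (-0.80, adjusted p = 0.0176). The next genes did not pass, among them Scrn2 at 0.98 (adjusted p = 0.0699), Sp6 at 1.15, Mrpl45 at -1.33 and Cpox, a heme synthesis enzyme, at -1.81. The count was 1 with beadchip as a block, 4 within beadchip 1 and 59 within beadchip 2 (57 lower in DKO), where KO is replicate 2 alone, and it lay between 1 and 4 when any of the 7 arrays was left out.

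**Figure D4:**
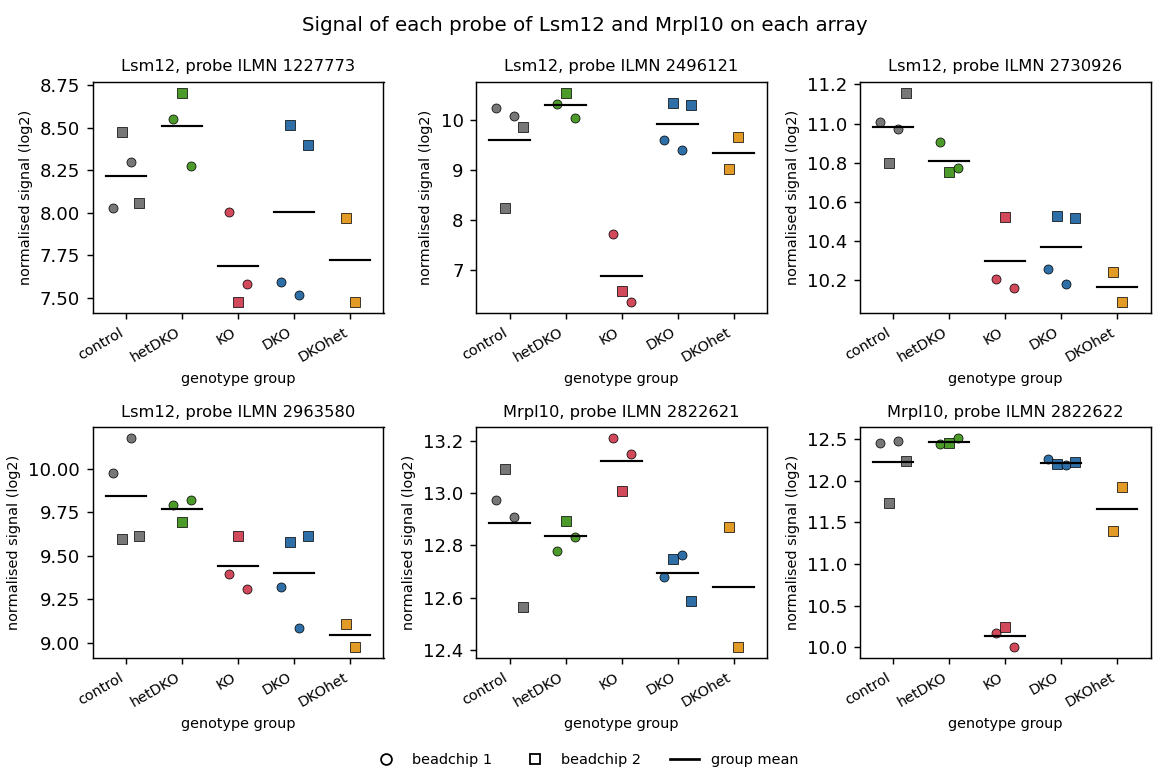
Normalised log2 signal (vertical axes) of each probe of Lsm12 and Mrpl10 on each of the 16 arrays, by genotype group, with circles for beadchip 1, squares for beadchip 2 and a line at the group mean. The probe ILMN_2822622 of Mrpl10 is at 10.14 in the mean of KO hearts and at 12.22 in DKO hearts, while the other Mrpl10 probe is at 13.12 and 12.69.

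DKO against DKOhet compares the loss of both Axin2 copies with the loss of 1 where Rbpj is deleted. Onecut2, a transcription factor, had a signal of 8.37 ± 0.24 (SD, n = 4) in DKO against 9.35 ± 0.15 (SD, n = 2) in DKOhet hearts, and Kcnh2, a cardiac potassium channel, 9.36 ± 0.14 against 9.92 ± 0.25, neither past the threshold. Rad50, a DNA repair protein, differed by 0.52 and Rerg, a small GTPase, by 1.30, also not past. None of 14058 probes passed with limma, against 551 at an unadjusted p under 0.05, where chance gives 703; none passed with beadchip as a block and 4 within beadchip 2. Leaving out DKO replicate 3 gave 1 probe and leaving out DKOhet replicate 2 gave 16.

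None of the list members passed in DKO against DKOhet, over all genes or adjusted over the list alone. Wnt target genes were 0.28 higher in DKO hearts (camera adjusted p = 0.0282, and adjusted p = 0.524 with an estimated correlation), 0.16 with beadchip as a block (adjusted p = 0.124) and 0.12 within beadchip 2 (adjusted p = 0.235). They did not pass without DKO replicate 3 (0.19) or DKOhet replicate 2 (0.20). Epicardium genes were at -0.36 (camera adjusted p = 0.0378, and adjusted p = 0.546 with an estimated correlation), -0.52 with beadchip as a block and -0.63 within beadchip 2. They did not pass without DKO replicate 1 (-0.32), DKO replicate 4 (-0.19) or DKOhet replicate 1 (-0.13), and were at -0.58 without DKO replicate 3 or DKOhet replicate 2. Unfolded protein and amino acid stress genes were at -0.26 (camera adjusted p = 0.0423, and adjusted p = 0.690 with an estimated correlation), -0.38 with beadchip as a block and -0.53 within beadchip 2, and turned to 0.29 without DKOhet replicate 1. The macrophage list was at -0.80 (camera adjusted p = 0.0423, and adjusted p = 0.593 with an estimated correlation), -0.97 with beadchip as a block and -1.07 within beadchip 2 (adjusted p = 0.115), and turned to 0.50 without DKOhet replicate 1. Nor did it pass without DKO replicate 2 (-0.64), DKO replicate 3 (-0.83) or DKO replicate 4 (-0.77), and it was at -2.10 without DKOhet replicate 2. The stress list did not pass without DKO replicate 1 (-0.23), DKO replicate 2 (-0.15) or DKO replicate 4 (-0.19) either, and was at -0.48 without DKO replicate 3 and -0.81 without DKOhet replicate 2. With only the arrays of these groups neither the stress list (adjusted p = 0.0599) nor the macrophage list (adjusted p = 0.0770) passed.

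Of the other lists, hepatic and yolk sac endoderm was at -0.43 in DKO against DKOhet (camera adjusted p = 0.0423, and adjusted p = 0.690 with an estimated correlation), -0.38 with beadchip as a block (adjusted p = 0.111) and -0.40 within beadchip 2 (adjusted p = 0.0515). It did not pass without DKO replicate 1 (-0.40), DKO replicate 2 (-0.33), DKO replicate 3 (-0.44) or DKOhet replicate 2 (-0.17), nor with array weights (-0.45), and was at -0.68 without DKOhet replicate 1. The p53 target list was at -0.16 (camera adjusted p = 0.0423, and adjusted p = 0.524 with an estimated correlation), -0.21 with beadchip as a block and -0.23 within beadchip 2 (adjusted p = 0.0533). Its call ended without DKO replicate 1 (-0.13), DKO replicate 2 (-0.15), DKO replicate 4 (-0.12) or DKOhet replicate 1 (-0.01), and with only the arrays of these groups (adjusted p = 0.0599); it was at -0.31 without DKOhet replicate 2. Oxidative phosphorylation was at -0.10 (camera adjusted p = 0.0430, and adjusted p = 0.524 with an estimated correlation), -0.08 with beadchip as a block (adjusted p = 0.129) and -0.10 within beadchip 2 (adjusted p = 0.149). That call ended whichever DKO or DKOhet array was left out: the mean was -0.09 without DKO replicate 1, -0.11 without DKO replicate 2, -0.11 without DKO replicate 3 and -0.10 without DKO replicate 4. It was -0.14 without DKOhet replicate 1 and -0.07 without DKOhet replicate 2. Nor did it pass with median scaling (-0.04), the stricter filter (-0.097) or the erythroid covariate (-0.10).

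Across the comparisons with control, 591 probes passed in KO, DKO and DKOhet hearts alike, 334 higher and 257 lower, none in opposite directions, and 415 of them also passed the same way in DKO against hetDKO. These comparisons share their control arrays, which alone makes their changes correlate. For KO and DKO the log2 changes correlated with r = 0.789, against 0.466 in simulations of unchanged groups, and with 0.437 to 0.604 when each was given its own control arrays. The covariance was 0.1289 against a simulated 0.02564, and 427 probes were higher and 393 lower in both, where 33.9 and 36.3 are expected of independent lists, a value that leaves out the shared controls. With no control array in common, 145 to 186 probes were higher and 56 to 90 lower in both. Independent lists of those sizes would share 5.7 to 11.6 and 3.1 to 9.2. Simulated unchanged groups shared 0.01 probes on average, but they leave few calls to share. That value is therefore no measure of the overlap between lists of called probes. For KO and DKOhet r was 0.752 (simulated 0.38, split controls 0.371 to 0.663), the covariance 0.1416 against 0.02554, and 351 probes were higher and 297 lower in both (21.8 and 24.1 for independent lists; 122 to 159 and 52 to 83 with split controls). For DKO and DKOhet r was 0.824 (simulated 0.412, split controls 0.451 to 0.699), the covariance 0.1478 against 0.02565, and 504 probes were higher and 413 lower in both (40.3 and 39.5 for independent lists; 165 to 214 and 93 to 136 with split controls).

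The changes of hetDKO hearts were set against those of the other genotypes in the same way. Against KO r was 0.373 (simulated 0.428, split controls -0.017 to 0.135) with a covariance of 0.03523 against 0.02541. Against DKO r was 0.316 (simulated 0.464, split controls -0.107 to 0.106) with a covariance of 0.02842 against 0.02553. Against DKOhet r was 0.223 (simulated 0.38, split controls -0.2 to 0.127) with a covariance of 0.02314 against 0.02553.

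Several lists had no call by camera in any comparison. Among 15 genes of the second heart field and pharyngeal mesoderm, 1 rose and 14 did not pass in KO hearts, and 1 rose and 1 fell in DKO hearts (camera adjusted p = 0.967). Fgf10, a growth factor of the pharyngeal mesoderm, was the gene that rose in DKO hearts, by 1.18 (adjusted p = 0.00309). Of 15 foregut and surface epithelium genes 1 rose in DKO hearts, the keratin Krt8, by 0.84, and 14 did not pass (camera adjusted p = 0.673). Of 6 neural crest genes 1 rose, 1 fell and 4 did not pass in DKO hearts (camera adjusted p = 0.673). None of 9 smooth muscle genes (camera adjusted p = 0.673) or 4 sex-linked transcripts (0.967) passed in DKO hearts.

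The median, the mean and the test of a list differed in sign in some comparisons without a call. In KO against control, Wnt components had a median of -0.05 and a mean of -0.02 with a test pointing up. In DKO against control the second heart field list had a median of 0.14 and a mean of -0.02, and the chamber list 0.04 and -0.05. In hetDKO against control they differed for the second heart field (0.014 and -0.01), endothelium (0.02 and -0.05), neural crest (-0.09 and 0.02) and stress response lists (-0.013 and 0.011), and the erythroid (0.001 and 0.011) and sex-linked lists (0.005 and 0.063) had tests pointing down. In DKOhet against control the second heart field list had -0.013 and 0.037, and the smooth muscle list, at -0.08 and -0.04, a test pointing up. In DKO against KO the Notch target (-0.005 and -0.024), second heart field (-0.09 and -0.009) and endothelium lists (-0.007 and -0.02) had tests pointing up and the epicardium list (0.009 and 0.007) a test pointing down. There the smooth muscle (0.002 and -0.04), foregut (-0.05 and 0.001) and p53 lists (-0.002 and 0.04) differed in sign too. In DKO against hetDKO this held for the Notch target (0.036 and -0.009), second heart field (0.08 and -0.013) and sarcomere lists (-0.023 and 0.033), and in DKO against DKOhet for the foregut list (0.117 and -0.044).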

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

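The tests on the Mrpl10 and Lsm12 probes, the test of the hypoxia and glycolysis list within each beadchip and the tests for a wrong label of KO replicate 2 were chosen after the result was seen, and the erythroid covariate behind the blood cell test was added after the data were seen.

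Sets of 4 arrays were searched for 1 array far from the other 3, and 5 of 110 sets held one, where chance flags about 1 in 20 (5.5 expected). Control replicate 4 was the highest control array for the Notch pathway components list (0.135, next -0.049), the oxidative phosphorylation list (0.193, next 0.002), Nrn1 (6.934, next 5.903) and Hspb3 (9.307, next 9.025). DKO replicate 3 was the highest DKO array for the cushion mesenchyme list (0.586, next 0.149).

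Lists that differed between DKO and KO hearts by camera were Wnt target genes (0.472), Wnt pathway components (0.172), BMP ligands and target genes (0.164), chamber and trabecular myocardium (0.265), cushion mesenchyme (0.308), erythroid cells (-1.19) and macrophages and other blood cells (-1.232). With an estimated correlation only the Wnt targets passed (adjusted p = 0.0478), and with fry none of these did (adjusted p = 0.0776 for the Wnt targets). The single probes that differed between these groups were 1 of Lsm12 (3.022) and 1 of Mrpl10 (2.079). For the same Mrpl10 probe, KO minus control differed from DKO minus hetDKO (-1.836, limma adjusted p = 0.0201). It was the only probe past the threshold in that test, against 709 at an unadjusted p under 0.05, where chance gives 703. HetDKO hearts already had 1 floxed copy of Rbpj, so these differences may not measure the same deletion.

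The first pattern is the low signal of that Mrpl10 probe and that Lsm12 probe in KO hearts, at 10.14 and 6.89, against 12.22 and 9.91 in DKO hearts; DKOhet hearts had 11.66 for the Mrpl10 probe, below control but not past the threshold (-0.57, adjusted p = 0.0759). A change of the whole transcript is argued against for the difference between DKO and KO by the other probes of both genes, whose highest upper 95% bound of DKO minus KO was 0.845. Both genes lie on chromosome 11 (Mrpl10 at 97041582, Lsm12 at 102162497), as does Axin2 (108917828). A strain haplotype around Axin2 stays open: of the 50 top genes of DKO against KO 12 were on that chromosome, 4.3 expected (one-sided Fisher exact p = 0.0007984, adjusted p = 0.01677 over 7 comparisons and 3 chromosomes), but without the 5 genes that raised the idea it was 7 of 45, 3.8 expected (p = 0.0829), and leaving them out was decided after the first value was seen. Loss of Axin2 whatever the state of Rbpj is argued against, since KO and control hearts both keep Axin2. The highest upper 95% bound of KO minus control over the 2 probes was -1.734. An effect of Axin2 loss only where Rbpj is deleted stays open. For the Mrpl10 probe KO minus control differed from DKO minus hetDKO (-1.836), and the Lsm12 probe did not pass that test. These values cannot tell such an effect from a haplotype that differs between the breeding groups.

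The next pattern is the higher hypoxia and glycolysis list in KO, DKO and DKOhet hearts. Beadchip is argued against, since the smallest difference from control within a beadchip was 0.929, and a different share of blood cells is argued against as the whole cause, since 14 of 17 members stayed past the threshold in DKO hearts with the erythroid list as a covariate (median 1.108 before and 0.958 after). The time between dissection and lysis stays open, because immediate early genes were higher as well (median 0.672 in DKO against control) and the labels give no dissection times. An effect of the Rbpj deletion, which these 3 groups share, stays open beside it and cannot be told apart from it here.

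The last pattern is KO replicate 2, which scored 45.8 on the third principal component. A control or hetDKO heart labelled as KO is argued against, since its hypoxia list median lay 0.765 of the way from control to the other KO arrays, and a DKO or DKOhet heart labelled as KO is argued against, since the lowest of those arrays lay at least 1.146 above it for the Mrpl10 and Lsm12 probes that are low in KO, probes that were called with this array among the KO arrays. Placental or maternal cells in that sample stay open: 3 of 7 measured markers (42.9%) were highest on that array, against 6.25% for a single marker by chance. Only Plac1 of the 5 trophoblast markers was among them (10.07, next 8.92), with the adult globins Hbb-b2 (12.13, next 10.45) and Hbb-bt (13.09, next 11.05), related genes that are not independent of each other, but placental genes picked after their values were seen, Prl3d3 (13.56, next 11.09), Prl8a2 (13.51, next 11.20), Rhox6 (10.85, next 7.94) and Cts7 (9.60, next 6.84), were highest there too. The design gives no biological explanation for this array alone, and none was tested.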

How the results depend on the processing

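The covariates for Eif2s3y and for the erythroid list were added after the results were seen, and erythroid list results under the erythroid covariate were dropped, after being seen, because that covariate fixes them at 0. Of 260 gene results, 250 kept their direction and side of the threshold without background correction, 249 with cyclic loess, 240 with median scaling, 253 with the deposited value table, 215 with no filter, 253 with beadchip as a block, 242 with array weights, 199 with the erythroid covariate, 185 with only the 2 groups compared and 34 within beadchip 2. It was 247 with the replicate block, 249 with trended and robust variance, 241 with the Eif2s3y covariate and 252 of 252 with the stricter filter. Within beadchip 1 it was 109 of 194, and with other probes of the gene 68 of 110, 1 of them reversed. Of 50 list results, 50, 50, 49, 50, 50, 45, 46, 39 (of 46), 47 and 33 did, in the order of the first 10 named, 47 with the replicate block, 50 with trended and robust variance, 49 with the Eif2s3y covariate, 45 with the stricter filter, 28 of 35 within beadchip 1, 30 with fry and 5 with an estimated correlation. With each array left out in turn 1372 of 1831 gene results and 292 of 345 list results did. The gene results cover only the named genes and the list members past the threshold, not all genes past it. Of these, 25 of 61 in KO, 26 of 77 in DKO and 40 of 66 in DKOhet against control were lost without some array. In DKO against hetDKO 25 of 56 were. The counts of list members that rose or fell therefore include genes that rest on single arrays. The number of arrays limits the precision.

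Within beadchip 1 the counts were 253 for KO against control, 456 for DKO against control, 4 for DKO against KO and 439 for DKO against hetDKO; within beadchip 2 they were 95, 22, 59 and 4, with 27 for DKOhet against control and 4 for DKO against DKOhet. With only the 2 groups compared they were 353 for KO, 260 for DKOhet and 2 for hetDKO against control. These fits use fewer arrays, yet some counts rose; the cause was not tested. Array weights gave 1858 for KO against control, 2933 for DKO against control and 1968 for DKO against hetDKO, and the erythroid covariate 702 for DKOhet against control and 690 for DKO against hetDKO; the cause was not tested. DKO against KO had 1 probe with no background correction, the deposited value table, no filter, beadchip as a block, trended and robust variance, array weights and either covariate; the cause was not tested.

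With 1 array left out the counts were 591 to 1057 for KO, 1040 to 1838 for DKO and 227 to 1737 for DKOhet against control, 1 to 4 for DKO against KO, 449 to 1005 for DKO against hetDKO and 0 to 16 for DKO against DKOhet. In DKO against DKOhet the list of macrophages and other blood cells ran from -2.102 to 0.503 and the unfolded protein and amino acid stress response list from -0.814 to 0.292, each positive without DKOhet replicate 1, where the lone sample is assumed to vary like the other groups. The chamber list in DKO against KO was -0.01 with the erythroid covariate and another probe of Tpi1 was at -0.182 in DKOhet hearts; the cause was not tested.

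The replicate block gave 1238 probes for KO, 2377 for DKO and 1709 for DKOhet against control, 1326 for DKO against hetDKO and 1 for DKO against KO. Under it the sarcomere list in hetDKO against control (-0.146) and the Wnt component (0.159) and BMP lists (0.157) in DKO against KO did not pass. Deviations of arrays with the same number from their group means correlated with a median r of 0.129 over 27 pairs (-0.009 to 0.346), and with other numbers -0.08 over 74 pairs, while arrays of the same beadchip had 0.127 and of different beadchips -0.124. All same-number pairs were above 0.1 between control and DKO (0.175 to 0.312) and between DKO and KO (0.127 to 0.241), but over all groups 18 of 27 were. Control replicate 3 correlated more with DKO replicate 1 (0.251) than with DKO replicate 3 (0.2), and most arrays of the same number share a beadchip. The numbers were therefore not used as pairs. The deviation of DKOhet replicate 1 correlated at -0.345 to -0.039 with even-numbered arrays of the other groups, which share its beadchip. With odd-numbered arrays, all on the other beadchip, it correlated at -0.009 to 0.367. Fits by beadchip may therefore place this array wrongly.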

Other observations

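No test in this part was planned except the splits of the arrays into groups.

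KO replicate 2 had 28 genes at least 2 log2 units above every other array and the other 15 arrays had 0. Rhox6, a placental homeobox gene of the Rhox cluster, stood at 10.85 against a next highest 7.94, the placental cathepsin Cts7 at 9.60 against 6.84, Rhox9 at 12.50 against 9.81 and Prl3d3, a placental gene of the prolactin family, at 13.56 against 11.09. These genes were chosen after their values were seen.

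Each grouping of the arrays of 2 groups into sets of the same sizes was tested in the same way, 35 groupings per comparison, the real one included. For KO against control the real grouping gave 1065 probes and the highest other 137, for DKO against control 1854 and 1, and for DKO against hetDKO 1105 and 3. In each of these 1 grouping, the real one, gave as many, so chance in how these arrays fell into groups is argued against. For DKO against KO the real grouping gave 2, the highest other 1 and 1 grouping as many, but the real count is 1 under several alternatives, so chance is not excluded there. For hetDKO against control the real grouping gave 0 and the highest other 1; a count of 0 is reached by all 35 groupings, so this test decides nothing.

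Eif2s3y, on the Y chromosome, was above 8 on 3 of 4 control, 1 of 3 KO, 2 of 4 DKO, 2 of 3 hetDKO and 1 of 2 DKOhet arrays. On the others it lay between 5.20 and 5.38, except for KO replicate 2 at 6.48. The sex-linked Kdm5d did not stand out on that array (5.43).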
